A study of Mus musculus with 6 samples.

How the data were processed

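RNA from the posterior part of mouse embryos at embryonic day 9.5 was measured on 6 one-colour CodeLink Mouse Whole Genome bioarrays, 3 wild type and 3 Splotch null. Groups came from the titles and the genotype field. The strain was labelled LMBc, a name the labels did not explain. Replicates were numbered in accession order within a genotype, and the numbers pair nothing.

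Per the labels' protocols, total RNA was amplified and labelled with biotin. Per the file headers, each array was read with CodeLink Expression Analysis 5.0.0.31312, and the deposited report held a raw intensity and an intensity normalized by the global median. The raw intensity went below 0 on all arrays, down to -16.6, so the authors' software had subtracted a background. How it did so is not given in the sources used here. Raw over normalized intensity was 1 constant per array, equal to the median of the 34967 discovery probes. The authors' deposited value table held intensity on a linear scale. It matched the normalized intensity times 1 constant per array, between 0.996 and 1.0035, within 1% for 100% of the positive spots, with negative and masked spots set to 0. All 6 of its columns had a median of 1.0363, and it was not centred by gene. The headers gave the same run of analysis for all arrays and no batch.

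From there, spots were taken with flag G (good), L (near background) or S (saturated), and spots with any other flag, 277 to 422 per array, were left out. The meaning of flag P was not given. The raw intensity was floored at 0.00595, below which values have no order, raised by 50, taken to log2 and quantile-normalized over discovery probes, because the deposited signal was already background-subtracted. Log2 differences therefore understate changes of dim genes. Of the probes, 24434 had flag G or S on at least 3 of 6 arrays and were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over the probes. A gene was represented by the probe with the highest mean. Where a probe was not above background on any array of a genotype, a fold is given only as a lower bound. Array medians were 3.87 to 5.72 times the trimmed mean of the negative controls.

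Genes were named from GEO's platform annotation, which can be old, updated by gene identifier to the symbols of the GRCm38.p6 annotation. This named 21487 probes, 128 kept their platform symbol, and 536 were named from the accession in the reports. Probes with several symbols (681) or none (12135) were left unnamed and entered the adjustment only. Of 13725 probes named both ways, 13717 had the same name. No genome build was given for the arrays, so no coordinates are printed. There were 7 unnamed probes with an unadjusted p under 0.01.

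Choices of test, gene lists and named genes were fixed before the data were examined. The named genes are Pax3; up to 12 genes per direction with the largest difference past the threshold and without overlap between genotypes; where fewer pass, up to 8 per direction with the smallest p among genes without overlap and at least 1.5-fold different; and up to 4 members with the smallest p from each list described. The genes naming the tissue, the sex-linked genes and those in the closing section chosen by variability or by their level on Splotch null 2 were picked from the lists or after their values were seen. Gene lists with at least 5 members were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, over genes measured on all 6 arrays. For 10 of the 36 lists, 0 of them called, the median, the mean and the direction of the test differed in sign. In some the median and the mean differed from each other, as for dermomyotome and muscle (0.028 and -0.025). Camera sets a list against all other genes, so its direction can also differ from both. The X-inactivation list had 4 members kept and was not tested. Exact permutation tests used all splits of the 6 arrays. The classifier used 50 probes per round.

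The procedure was tested on simulated data with the arrays' own spreads for the comparison of Splotch null with wild type. Of 200 genes changed 2-fold among 23319 probes, 48.5% were recovered with 8 false calls. Of 200 changed 4-fold, 92% were recovered with 18 false calls. The simulated noise was independent between genes.

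Alternatives were median scaling, cyclic loess, the authors' normalized intensity, the authors' value table, offsets of 10 and 200, no filter, a filter on all 6 arrays, trended and robust eBayes, array weights, the mean of a gene's probes, Y-linked level as a covariate, sex-linked genes left out, each array left out, 20 or 200 classifier probes, an unadjusted threshold and the other list tests. Settings with log2 array median as a covariate, or without the 2 brightest arrays, were chosen after the data were seen. Control spots entered no comparison. Figures were drawn with matplotlib 3.10.9.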

Results

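Gene expression was measured in the posterior part of mouse embryos at embryonic day 9.5, a stage at which the spinal neural tube is still open at its caudal end. The 6 arrays fell into 2 genotypes, with 3 wild-type and 3 Splotch null samples. Splotch is a mutation of Pax3, a paired-box transcription factor of the dorsal neural tube, the dermomyotome and the neural crest, and embryos that lack Pax3 function develop spinal neural tube defects. The labels did not state whether an array held 1 embryo or several, so the p-values below speak only for these samples. Those of limma rest on the spread between samples, which may be partly technical. Those of camera with a preset correlation set the genes of a list against all other genes. They rest largely on the spread between genes and do not measure replication across samples. Each array was a one-colour CodeLink bioarray with 34967 probes for transcripts, of which 66.1% to 71.7% lay above background. The median background-subtracted intensity ranged from 84.3 on wild type 3 to 121.1 on Splotch null 3. The number of arrays limits the precision of all comparisons.

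The labels named the tissue in 2 ways, since one field gave the anterior neural tube and the tissue field, the series title and the dissection protocol gave the posterior part. Genes of the caudal embryo were bright on the arrays. Hoxd11, a caudal Hox gene, had a mean log2 intensity of 11.64 over the 6 arrays, and Cdx2, a homeobox gene of the tail bud, had 11.14. T, the mesoderm gene brachyury, had 12.16 over the 5 arrays on which its spot was usable. Of 30 genes listed for the brain and anterior neural tube, 18 were above background on all 6 arrays and 8 on none. The forebrain genes Otx2 and Emx1 were among those on none. Six3, a gene of the anterior forebrain, was above background on all 6 arrays with a mean of 11.04, as were the pituitary gene Hesx1 at 7.10, the eye field gene Rax at 6.98 and the midbrain and hindbrain gene En2 at 7.29.

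The first comparison asked which genes differed between Splotch null and wild-type posterior embryos. Pax3 itself was expressed in both genotypes at similar levels. The brighter Pax3 probe had a mean log2 intensity of 10.45 ± 0.41 (SD, n = 3) in wild type and 10.62 ± 0.099 (SD, n = 3) in Splotch null. The difference was 0.17 (SE 0.21, 95% confidence interval -0.32 to 0.66), with an exact two-sided permutation p of 0.6, where the smallest p that 3 against 3 allows is 0.1. The other Pax3 probe differed by -0.091 (SE 0.20), with an exact permutation p of 0.8. The allele was not given in the labels, so a transcript level at these probes does not check the mutation. Without wild type 1 the difference of the brighter probe was -0.050. Without wild type 1 and Splotch null 3, the 2 brightest arrays, a setting chosen after the data were seen, it was -0.053.

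No gene passed the threshold in this comparison, and the genes named next are those with the smallest p among genes whose genotypes did not overlap and differed by at least 1.5-fold. Sox10, the transcription factor of migrating neural crest and glia, was 2.18-fold dimmer in Splotch null than in wild type. Its log2 intensity was 8.03 ± 0.30 (SD, n = 3) in wild type and 6.90 ± 0.025 (SD, n = 3) in Splotch null, a difference of -1.13 (SE 0.17). Sox10 differed by -1.28 between the 2 brightest arrays, which are 1 of each genotype, and by -1.05 between the other 4. Its size depended on the offset added before log2, with -1.47 at an offset of 10 and -0.61 at 200. The LIM-homeobox genes Lhx2 and Lhx9 differed by -1.13 (SE 0.26) and -1.11 (SE 0.25), and Lhx9 was above background on only 1 of the 3 null arrays. Between the 2 brightest arrays Lhx2 differed by -1.98 and Lhx9 by -1.91, and between the other 4 by -0.71 and -0.72. Tfap2c, an AP-2 transcription factor of surface ectoderm and germ cells, differed by -0.77 (SE 0.15). Tcf15, the paraxis gene needed for epithelial somites, differed by -0.90 (SE 0.27), and by -0.59 without wild type 3. The keratin Krt23 differed by -0.81 (SE 0.21), the lymphatic growth factor Vegfd by -0.77 (SE 0.23) and the secreted ligand Bmp3 by -0.59 (SE 0.14). Vegfd differed by -1.39 between the 2 brightest arrays and by -0.46 between the other 4. The size of other genes also depended on the setting. Over the settings run, Lhx9 lay between -1.76 and -0.50, Krt23 between -1.15 and -0.39 and Bmp3 between -0.85 and -0.28.

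Genes brighter in Splotch null included Foxd1, a forkhead gene of renal stroma and mesenchyme, with a difference of 0.87 (SE 0.25). This was 1.54 between the 2 brightest arrays and 0.53 between the other 4. Pax8, a paired-box gene of the early kidney, was not above background on any wild-type array and was above it on all 3 null arrays, at least 1.52-fold higher. Dipk2a was likewise not above background in wild type and at least 1.27-fold higher in Splotch null. These bounds, at the chosen offset, set the null mean against the higher of the probe's own signal and the dimmest signal above background on each wild-type array. The matrix proteoglycan Dcn differed by 0.61 (SE 0.20) and the lysosomal amidase Naaa by 0.60 (SE 0.21). The peroxisomal import gene Pex13 differed by 0.65 (SE 0.23), Cyb5rl by 0.63 (SE 0.21) and Patl2 by 0.62 (SE 0.22). Pex13 differed by 1.42 between the 2 brightest arrays and by 0.27 between the other 4, Cyb5rl by 0.22 and 0.84, and Patl2 by 0.39 without wild type 2. All 16 genes were selected for a lack of overlap, which fixes their exact permutation p at 0.1.

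**Figure D1:**
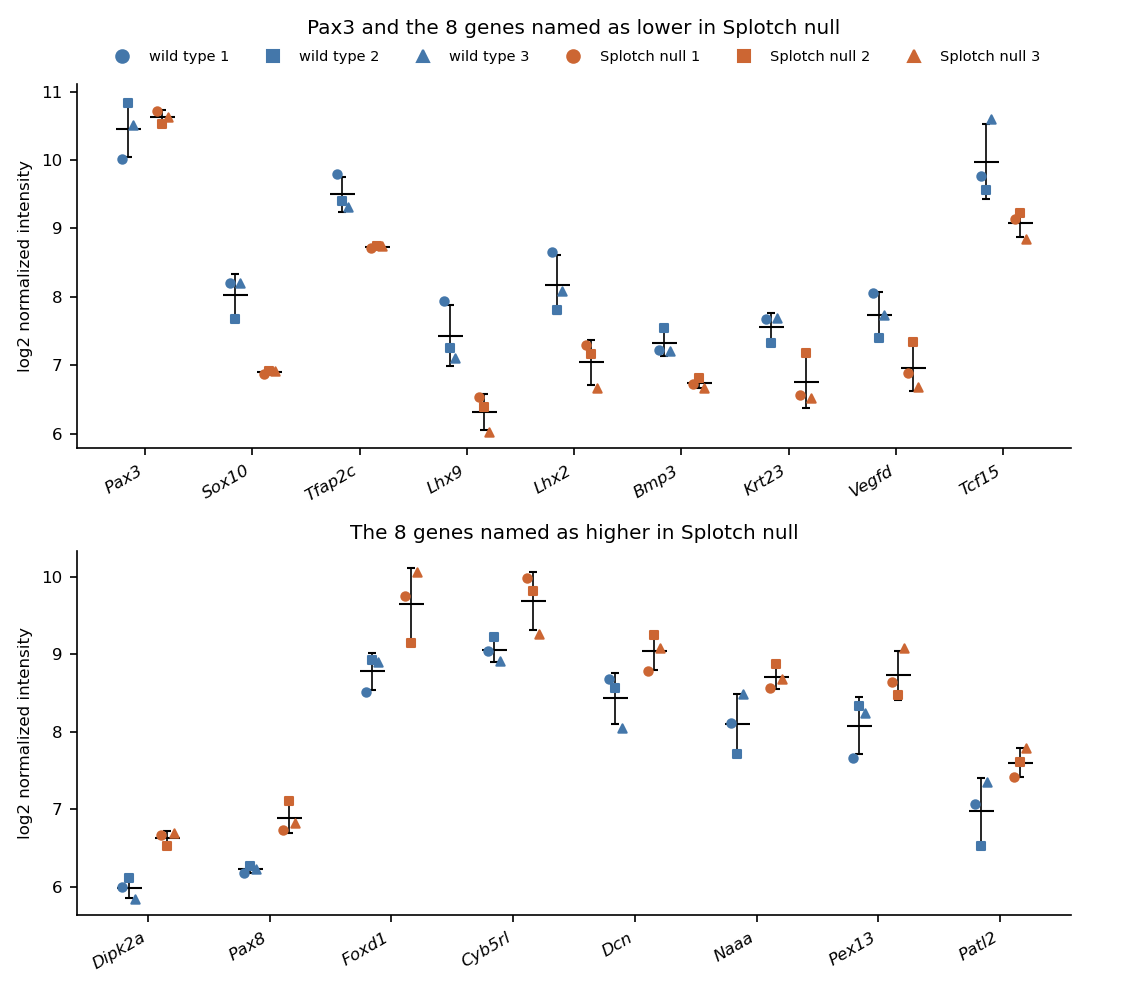
Log2 normalized intensity (vertical axis) of Pax3 and the 16 named genes on each array, wild type in blue and Splotch null in orange, with a marker shape per replicate; bars are group means with SD (n = 3). The Sox10 signal lies at 6.87 to 6.92 on the 3 null arrays and at 7.68 or above on the 3 wild-type arrays, while the Pax3 groups overlap.

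Among 14315 genes tested with limma, 0 had a Benjamini-Hochberg adjusted p under 0.05, and the lowest adjusted p rounded to 1. An unadjusted p under 0.05 was reached by 204 genes, or 1.43%, where chance gives about 716 on average. Of the 204, 143 were brighter in Splotch null. Genes are not independent, and other splits of the 6 arrays into 3 and 3 gave from 47 to 3820 such genes. With log2 array median as covariate, chosen after the data were seen, there were 676, or 4.72%. The shortfall against 716 is therefore no finding about genotype. With an unadjusted p under 0.01 and at least a 1.5-fold difference there were 9 genes, 3 brighter and 6 dimmer in Splotch null. That count was 16 without wild type 2, 29 without wild type 3, 23 without Splotch null 2 and 33 without Splotch null 3. The genotypes did not overlap for 703 genes, or 5.11% of those measured on every array, where chance gives 10% on average. The same dependence between genes bears on this share.

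The second comparison took the genes by group, using 37 lists fixed before the data were examined, of which 36 had at least 5 measured members. With camera and a preset correlation, 6 lists passed an adjusted p of 0.05, and 3 of them were shifted up and 3 down in Splotch null. With a correlation estimated per list 0 lists passed, the lowest adjusted p being 0.469, and with fry 0 passed, the lowest being 0.953. No member of any list passed the threshold over all genes. Where a member is said below to pass over the list alone, the adjustment was not corrected for the number of lists. The same gene can pass in several lists.

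The neural crest list was shifted down, with 19 of 27 measured members dimmer in Splotch null, a mean log2 difference of -0.11 and a median of -0.055 (camera adjusted p = 0.00898; adjusted p = 0.469 with an estimated correlation). Sox10 was the 1 member that passed when adjusted over the list alone (limma adjusted p = 0.00653). Tfap2b, an AP-2 factor of crest and ectoderm, differed by -0.39 (SE 0.15) and did not pass (limma adjusted p = 0.474 over the list alone). Camera no longer called the list without wild type 3 (adjusted p = 0.101, mean difference -0.066) or without Splotch null 3 (adjusted p = 0.0969, mean difference -0.063).

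The intermediate mesoderm list, which holds genes of the early kidney and gonad, was shifted up, with 13 of 17 members brighter in Splotch null and a mean difference of 0.21 (camera adjusted p = 0.000396; adjusted p = 0.469 with an estimated correlation). Pax8 passed when adjusted over the list alone (limma adjusted p = 0.028). Wt1, the Wilms tumour gene, differed by 0.52 (SE 0.15) and Lhx1, a LIM-homeobox gene of the nephric duct, by 0.22 (SE 0.13). Neither passed over the list alone. Camera called this list with each array left out in turn.

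The tail bud list was also shifted up, with 20 of 24 members brighter in Splotch null and a mean difference of 0.13 (camera adjusted p = 0.00548; adjusted p = 0.831 with an estimated correlation). Msgn1, a transcription factor of presomitic mesoderm, differed by 0.33 (SE 0.16), Wnt5b by 0.24 (SE 0.12) and Fgf17 by 0.22 (SE 0.12), and 0 members passed over the list alone. The call was lost without wild type 1 (camera adjusted p = 0.0871), without Splotch null 1 (0.111) or without Splotch null 3 (0.12). The Hox paralogs 10 to 13 had 8 of 9 members brighter, led by Hoxa10 at 0.46 (SE 0.24), and were not called under the chosen processing (camera adjusted p = 0.0876). They were called up in 7 of 22 other settings, among them without Splotch null 2 (0.000254), without wild type 2 (0.00424), and with median scaling (0.0469), the authors' normalized intensity (0.0482), the authors' value table (0.0464) or the mean of a gene's probes (0.037).

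The sclerotome list was shifted down, with 9 of 13 members dimmer and a mean difference of -0.19 over the 11 members measured on all arrays (camera adjusted p = 0.025; adjusted p = 0.883 with an estimated correlation). Tbx18, a gene of the anterior somite compartment, differed by -0.25 (SE 0.14). Leaving out wild type 1 (camera adjusted p = 0.102), Splotch null 1 (0.06), wild type 3 (0.291) or Splotch null 2 (0.0985) ended the call. The mean difference was -0.11 without wild type 3 and between -0.172 and -0.155 without each of the other 3 arrays just named.

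The surface ectoderm list was shifted down, with 19 of 27 members dimmer and a mean difference of -0.10 (camera adjusted p = 0.00898; adjusted p = 0.883 with an estimated correlation). Tfap2c passed when adjusted over the list alone (limma adjusted p = 0.0368). The epithelial transcription factor Grhl2 differed by -0.31 (SE 0.17) and Sfn, the 14-3-3 protein of stratified epithelium, by -0.25 (SE 0.14). The call was lost without wild type 1 (camera adjusted p = 0.425), without Splotch null 1 (0.347) or without Splotch null 3 (0.0974). The mean difference was -0.29 between the 2 brightest arrays and -0.021 between the other 4, and it was -0.034 without wild type 1 and -0.035 without Splotch null 1.

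The visceral endoderm and yolk sac list was shifted up, with 20 of 23 members brighter in Splotch null and a mean difference of 0.51 (camera adjusted p = 0.00898; adjusted p = 0.883 with an estimated correlation). Many of its genes encode serum and lipid-transport proteins of the extraembryonic endoderm and liver. One array set this value. The mean of the list was 10.85 on Splotch null 2 and between 8.09 and 8.78 on the other 5 arrays. Afp, alpha-fetoprotein, had a log2 intensity of 13.19 on Splotch null 2 and at most 9.52 elsewhere, and Apoa1, an apolipoprotein, had 13.80 and at most 9.80. Trf differed between genotypes by 1.10 (SE 0.65) and Apoc2 by 2.0 (SE 1.44). Without Splotch null 2 the list was called in the opposite direction, with a mean difference of -0.337 (camera adjusted p = 0.00019). It was not called without wild type 1 (0.0871) or wild type 3 (0.101).

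**Figure D2:**
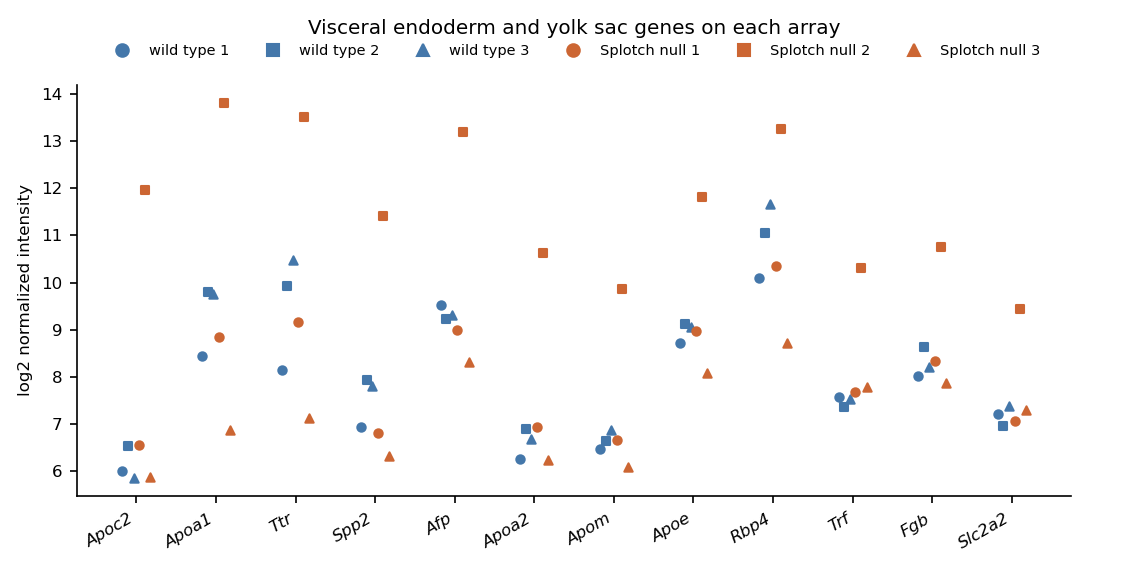
Log2 normalized intensity (vertical axis) of the 12 members of the visceral endoderm and yolk sac list with the largest excess on Splotch null 2, on each array, wild type in blue and Splotch null in orange. Splotch null 2, the orange square, is the highest array for each of the 12 genes, with Afp at 13.19 and Apoc2 at 11.97.

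The lists closest to Pax3 and to neural tube closure were not called with all 6 arrays. Of 18 PAX3-associated genes, 11 were dimmer and 7 brighter (camera adjusted p = 0.288). Met, the receptor of migrating muscle precursors, differed by -0.20 (SE 0.11) and Wnt1, of the dorsal midline, by -0.17 (SE 0.12), both with no overlap between genotypes. Dermomyotome and muscle genes split 13 to 12 (adjusted p = 0.61), with Tcf15 at -0.90 and the skeletal actin gene Acta1 at 0.55 (SE 0.16). Presomitic mesoderm and segmentation genes had 17 of 28 members dimmer (adjusted p = 0.107). Of 72 mouse neural tube defect genes, 41 were dimmer (adjusted p = 0.241), with the BMP antagonist Nog at -0.31 (SE 0.14). The glycine cleavage gene Gldc, also on the list of folate and one-carbon metabolism (adjusted p = 0.564), differed by 0.26 (SE 0.13). Without Splotch null 3, camera called the PAX3-associated genes (adjusted p = 0.0454), the presomitic genes (0.00915) and the neural tube defect genes (0.0159) down. The same 3 lists were called down without the 2 brightest arrays (0.0131, 0.00179 and 0.0131), and the presomitic genes also without wild type 2 (0.00289). All these calls used the preset correlation. With a correlation estimated on all 6 arrays, camera gave an adjusted p of 0.883 for each of the 3 lists.

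Within the neural tube, genes of the dorsal part (camera adjusted p = 0.564), of the ventral part, floor plate and notochord (0.817), of neural progenitors (0.223) and of neurons (0.118) were not called under the chosen processing. The dorsal genes Msx1 and Zic2 differed by -0.41 (SE 0.23) and 0.44 (SE 0.26). Over the other settings Msx1 lay between -0.60 and -0.079 and Zic2 between 0.14 and 0.60. Shh, the floor plate signal, differed by 0.43 (SE 0.20). Among neuronal genes 19 of 26 were brighter in Splotch null, with the motor neuron gene Isl1 at 0.32 (SE 0.14) and Nhlh2 at 0.29 (SE 0.12), while Lhx9 was dimmer. Neural progenitor genes were called up without Splotch null 2 (camera adjusted p = 0.00633, mean 0.168) and down without Splotch null 3 (0.000663, mean -0.249). Neuronal genes were called up without Splotch null 2 (4.78e-05), without wild type 3 (0.0268) and with the filter on all 6 arrays (0.0113), and ventral genes without Splotch null 2 (0.0156). All these calls used the preset correlation. Estimated on all 6 arrays, the correlation was 0.221 for neurons, 0.444 for neural progenitors and 0.113 for ventral genes. Camera then gave adjusted p of 0.883, 0.883 and 0.91. Lhx2 passed when adjusted over the brain list alone (limma adjusted p = 0.0283), as did Pax8, and the list as a whole was not called (camera adjusted p = 0.926).

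**Figure D3:**
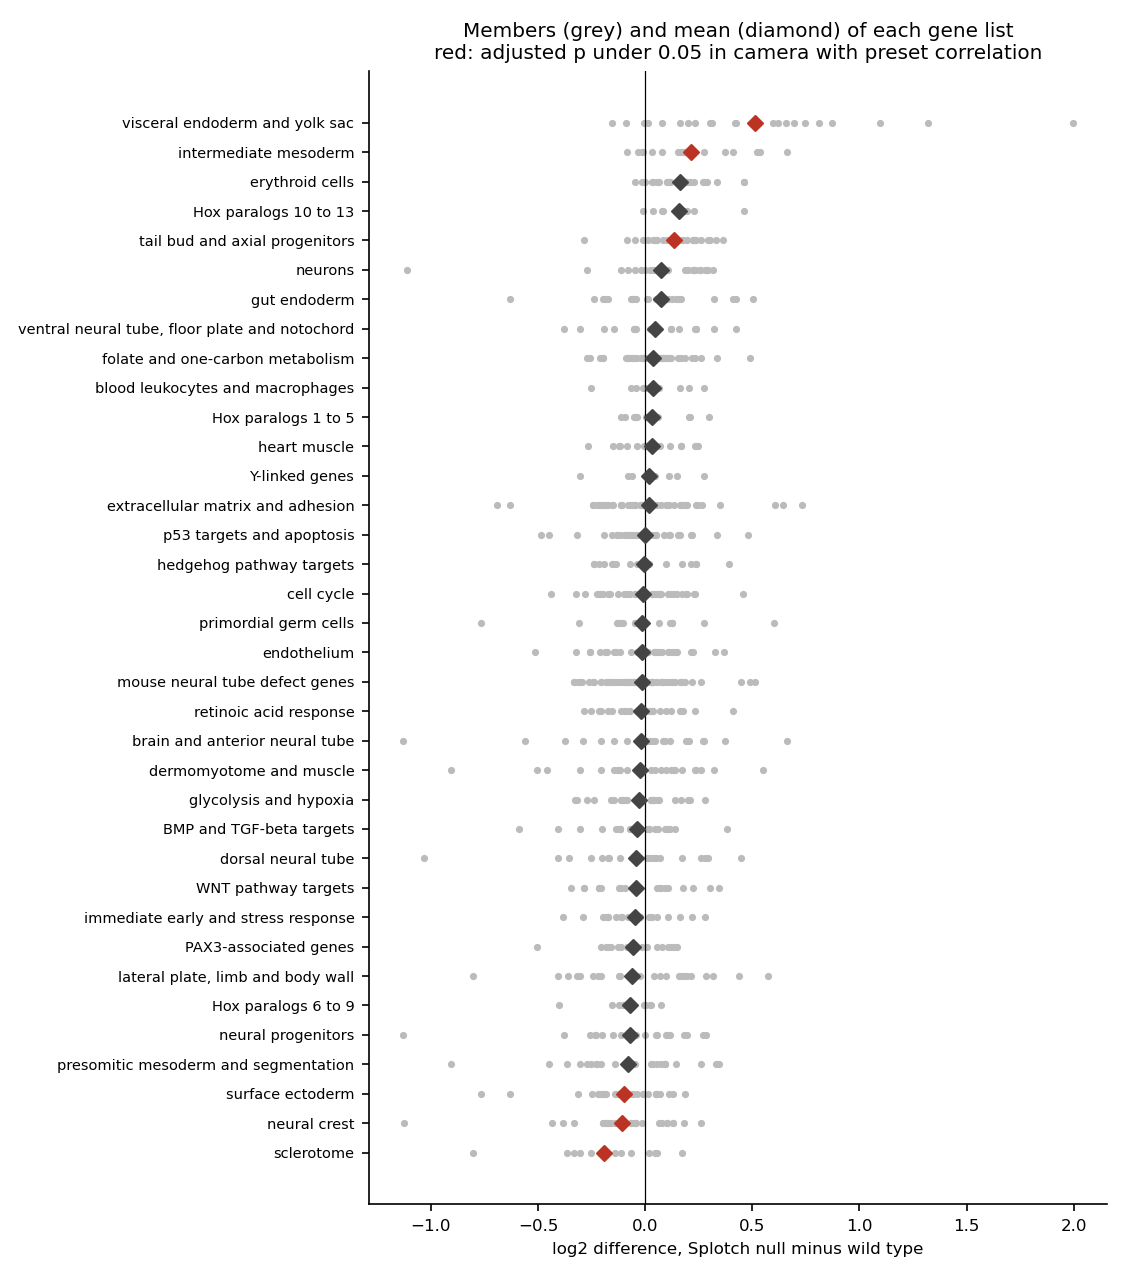
Log2 difference, Splotch null minus wild type (horizontal axis), for the members of 36 gene lists (grey points) and their means (diamonds), with n = 3 arrays per genotype; red marks the 6 lists with an adjusted p under 0.05 in camera with a preset correlation. The widest spread of members, up to 2.0 for Apoc2, is in the visceral endoderm and yolk sac list.

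The study also compared the samples individually and sought classifiers, so the third comparison asked whether arrays of one genotype resembled each other. They did not do so more than arrays of different genotype. The mean Pearson correlation across 23319 probes was 0.977 for the 6 pairs of arrays of the same genotype and 0.980 for the 9 pairs of different genotype. The difference of -0.00383 had an exact one-sided permutation p of 0.7 over the 10 splits. The closest pair was Splotch null 1 and wild type 3, with a correlation of 0.993 across probes, which are not independent replicates. The most distant pair was Splotch null 2 and Splotch null 3 at 0.959, both of one genotype. Without Splotch null 3 the difference was 0.00108.

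A nearest-centroid classifier on the 50 probes with the smallest limma p in 5 arrays assigned 3 of the 6 left-out arrays to their own genotype. The exact one-sided permutation p was 0.6, where 10 splits allow no p below 0.1. Wild type 1, wild type 2 and Splotch null 1 were assigned to their own genotype, and wild type 3, Splotch null 2 and Splotch null 3 to the other.

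The first component of variation held 61.9% of the variance and followed the brightness of the arrays. Over the 6 arrays it correlated with log2 array median at Pearson's r = 0.976 (exact permutation p = 0.00833) and Spearman's rho = 0.829 (exact permutation p = 0.0583). Without the 2 arrays farthest from the median brightness r was 0.822. Wild type 1 and Splotch null 3 lay at one end of the component, at 0.53 and 0.56, and Splotch null 2 at the other, at -0.49.

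**Figure D4:**
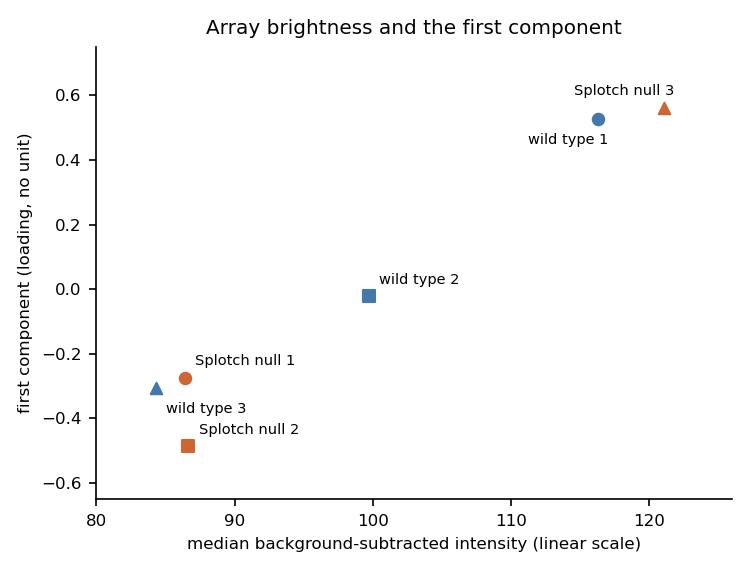
First component of the normalized log2 values (vertical axis, no unit) against the median background-subtracted intensity of each array (horizontal axis, linear scale), wild type in blue and Splotch null in orange. The 2 brightest arrays, with medians of 116.3 and 121.1, are 1 of each genotype and lie together.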

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

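The settings with log2 array median as covariate or without the 2 brightest arrays were chosen after the data were seen. Under limma 0 genes passed the adjusted threshold in every setting run, and 9 passed the unadjusted one. Each of the 48 genes tracked kept its direction in all settings that measured it. They were picked on these same arrays, for a lack of overlap between genotypes or for a small p. Where the genotypes did not overlap, leaving out arrays cannot reverse the sign, so the kept directions are no independent support. The unadjusted count was 26 with an offset of 10, 3 with an offset of 200, 35 with array weights, 26 with the covariate, 33 without the 2 brightest arrays and 71 with the covariate and without Splotch null 2, with genes at an unadjusted p under 0.05 between 113 and 988. It was 10 to 33 with single arrays left out. Called lists numbered 0 with an estimated correlation and 0 with fry, 3 to 15 with single arrays left out, 12 without the 2 brightest arrays and 13 without Splotch null 2 with the covariate. Of the 6 called lists, intermediate mesoderm passed in all 22 settings that kept the preset correlation, neural crest in 19, tail bud and surface ectoderm in 18 each, sclerotome in 15 and visceral endoderm in 15. Median scaling, the authors' normalized intensity and the authors' value table each scale an array by 1 constant, so the 22 settings are not independent. The visceral endoderm list mean was 1.04 without Splotch null 3 and turned to -0.337 without Splotch null 2 and to -0.301 with the covariate as well, since that array holds its high values. Pax3 lay between -0.050 and 0.35 with single arrays left out and at -0.053 without the 2 brightest arrays. Its other probe lay between -0.31 and 0.022, positive without wild type 2 (0.012) or wild type 3 (0.022). The correlation difference lay between -0.00666 and 0.00108, positive without Splotch null 3. The classifier assigned 2 or 3 arrays correctly. For the other changes the cause was not tested. No paired analysis was possible because the replicate numbers follow accession order only. Of the 30 lists not called under the chosen processing, some were called in other settings, and neural progenitors, endothelium, gut endoderm and lateral plate in either direction depending on the array left out or the setting. Signal over background limited dim genes.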

Other observations

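Sex-linked genes separated the arrays in a way that crossed the genotypes. The Y-linked gene Eif2s3y had a log2 intensity of 11.34 to 12.02 on 4 arrays, and 6.51 on wild type 2 and 6.10 on Splotch null 2. Xist, the RNA that coats the inactive X chromosome, had 10.55 and 9.10 on those 2 arrays at one probe and at most 6.02 on the others. Its other probe stayed at 6.03 or below on all arrays. Each genotype thus held 1 array with low Y-linked and high Xist signal. No array had both signals high, which argues against pools of embryos of both sexes. Single embryos and pools of 1 sex cannot be told apart. Among the 30 genes that varied most over the 6 arrays, chosen after their values were seen, 3 were Y-linked, 10 were on the visceral endoderm and yolk sac list and 21 were highest on Splotch null 2. Dbx1, a gene of interneuron progenitors, was 7.03 on Splotch null 2 and 8.73 to 11.12 elsewhere, and Zic1, of the dorsal neural tube, was 7.27 there and 8.71 to 10.15 elsewhere.

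The remaining lists, of other tissues and pathways, were not called with camera under the chosen processing. The embryonic globins Hbb-y and Hba-x differed by 0.46 (SE 0.24) and 0.34 (SE 0.25), and 21 of 24 erythroid genes were brighter in Splotch null (adjusted p = 0.0676). Between the 2 brightest arrays the erythroid mean differed by -0.491, and between the other 4 by 0.493. Lateral plate and limb genes (0.401) included Wnt2b at 0.44 (SE 0.14), above background on 2 of 3 wild-type arrays. BMP and TGF-beta targets (0.489) included Bmp7 at -0.59 (SE 0.20) and Id4 at 0.38 (SE 0.14), and WNT targets (0.189) included Tcf7 at -0.28 (SE 0.13). Gadd45a, among p53 targets (0.564), differed by -0.49 (SE 0.17). Adjusted p was 0.51 for the cell cycle, 0.51 for hedgehog targets, 0.564 for retinoic acid response, 0.871 for Hox paralogs 1 to 5, 0.223 for Hox paralogs 6 to 9, 0.573 for extracellular matrix, 0.564 for endothelium, 0.564 for leukocytes, 0.802 for heart muscle and 0.564 for gut endoderm. It was 0.305 for primordial germ cells, where Tfap2c passed over the list alone (limma adjusted p = 0.0246), 0.189 for immediate early genes, 0.394 for glycolysis and hypoxia and 0.564 for Y-linked genes. Other settings brought calls, all with camera at the preset correlation of 0.01. With all 6 arrays the estimated correlation was 0.326 for the erythroid list and 0.467 for the cell cycle list. Camera with those correlations gave adjusted p of 0.883 and 0.899, so the small p-values below rest on the preset. Erythroid genes were called up with array weights (0.00266), with the mean of a gene's probes (0.0358) and with log2 array median as covariate (0.0467), and cell cycle genes down with array weights (0.0272). Erythroid genes were also called up without wild type 1 (3.03e-20) or Splotch null 3 (0.0436), and cell cycle genes again down without Splotch null 3 (0.000142). Endothelium was called down without Splotch null 2 (0.00707) and up without Splotch null 3 (0.00915), as was gut endoderm (0.0345 and 0.0206). Without Splotch null 2, lateral plate (0.00291), BMP and TGF-beta targets (0.022), germ cells (0.0293) and immediate early genes (0.0432) were called down. So were germ cells without wild type 1 (0.00772), immediate early genes without wild type 2 (0.00489) and extracellular matrix without wild type 3 (0.0407).

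The tests in the paragraphs below were put to these patterns after the results were seen, although leaving out each array was a planned setting. The 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 0 genes past the threshold, a count that all 10 splits reach by definition, so it tests nothing, and the highest other gave 523. That split sets wild type 1, wild type 2 and Splotch null 3, the 3 brightest arrays, against the rest. Whether this structure came from the samples or from the arrays was not tested. With log2 array median as covariate 0 genes passed for genotype. The real split gave 6 called lists, reached by 7 splits, and the highest other gave 18. It gave 9 genes at an unadjusted p under 0.01 and 1.5-fold, reached by 7 splits, and the highest other gave 580.

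Wild type 1 and Splotch null 3 stood apart on the first component. Genotype took 2.66% of that component's variance, which argues against genotype as its source. Labelling or hybridization of those arrays stays open: 73.3% of the 30 positive control probes were lower on both arrays than on the other 4, with a median difference of -0.565 over all 30, although what these probes bind is not given in the sources used here. Age of the embryos or the level of dissection stays open, because the labels give neither per array. The Hox paralogs 10 to 13 differed by -0.0449 on average between these arrays and the other 4. Against the 3 others without Splotch null 2, both arrays were lower for visceral endoderm (-0.417, or -0.962 with that array among the others). Both were also lower for germ cells (-0.4), heart muscle (-0.362), gut endoderm (-0.268) and neural crest (-0.14). Both were higher for the cell cycle (0.335), extracellular matrix (0.222), glycolysis and hypoxia (0.159) and Y-linked genes (0.754). Wild type 2, with low Y-linked and high Xist signal, set most of the Y-linked value. Its list mean was 7.379, against 9.05 on Splotch null 1 and 9.065 on wild type 3. On wild type 1 and Splotch null 3 it was 9.139 and 9.364. With 2 arrays set against 3, some lists would lie outside by chance, and this was not tested. The erythroid excess was on wild type 1 (10.1) and not on Splotch null 3 (9.61).

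Sox10 was the gene with the smallest p. It differed by -1.28 between the 2 brightest arrays and by -1.05 between the other 4. Sox10 was picked for a lack of overlap and both sets held both genotypes, so both signs were fixed beforehand. These differences are therefore no independent test of brightness of the arrays as the cause. With log2 array median as covariate the difference was -1.12 (SE 0.157). Each genotype held bright and dim arrays, so that covariate could hardly move it. Extra tissue in Splotch null 2 alone does not account for Sox10 levels as low on Splotch null 1 (6.87) and Splotch null 3 (6.92) as there (6.92). The rule that picked Sox10 required low levels on all 3 null arrays, so this is no independent test. Without Splotch null 2 the difference was therefore -1.13 (SE 0.203). A candidate explanation is fewer neural crest cells in the Splotch null samples. The median of the other 26 crest list members was -0.0555 (interquartile range -0.176 to 0.0744), with 18 lower. The members together thus did not fall by as much as Sox10. Of the 26, 8 are on other lists, and the data do not show that the rest are made only by crest cells. Their level therefore need not follow crest cells, and the explanation stays open. Some gene had as small a p in 6 of the 10 splits, with 2.07e-05 the smallest in another split against 0.000242 for Sox10, and 10 splits are too few for a share under 0.05. The pattern is a hypothesis for a new set of embryos.

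Yolk sac genes were high on Splotch null 2. A single scale factor on that array is argued against by a median of -0.069 over all genes relative to the other arrays, on log2 intensities without normalization, where the list mean was 2.28 higher, and genotype by a list mean that differed by -0.337 between Splotch null 1 and 3 and wild type. Yolk sac or liver tissue in that sample stays open, because the share of the 23 listed genes that were highest there, 82.6%, with Apoa1 at 13.80 and Ttr at 13.51, only restates the pattern. The excess was not confined to these genes. Gut endoderm was higher there by 0.477 on average (13 of 25 kept members highest) and endothelium by 0.352 (13 of 30). Heart muscle was higher by 0.315 and germ cells by 0.31. The averages are over members measured on all arrays. The neural progenitor list differed by -0.617, with 0 of 23 members highest there, so a different share of several tissues stays open.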
